A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

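The series is a chromatin immunoprecipitation sequencing (ChIP-seq) study of Gcr1, the transcription factor that activates glycolytic genes in budding yeast. Per the labels, Gcr1 carried a tandem affinity purification (TAP) tag in the BY4741 laboratory strain of Saccharomyces cerevisiae, a haploid derived from the reference strain S288C, and bound chromatin was recovered on IgG-sepharose. Gcr1(U) is the form made from the transcript that keeps the intron, and Gcr1(S) the form made from the spliced transcript. Cultures were started at an OD600 of 0.5 in rich medium with 2% glucose at 30 °C, and cells were fixed with 1% formaldehyde for 25 min at 6 h or at 12 h. Per the labels the libraries had 15 cycles of PCR and were read from 1 end for 50 cycles. The 8 samples form 4 groups of 2 replicates, Gcr1(U) and Gcr1(S) at each of the 2 times. No input or untagged library was analysed here, so signal that does not depend on Gcr1 has no measured background.

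There was 1 peak list per form and time, 4 in all, with no value per replicate. The submitters' processing notes name the genome build sacCer3 and the tools bcl2fastq 1.8.2, FastQC 0.10.1, BWA 0.7.15, Picard 2.92, HOMER and bedtools, without their roles or order. Per the file headers, the lists come from HOMER's findPeaks. The signal the authors deposited for each peak is a normalized tag count, the tags in that peak's window scaled to library size. The deposited score is the findPeaks score, used here only to rank the peaks within a list. The fold over local background and the p-value against it are those of the authors' peak caller. The focus ratio, a fraction, and the clonal fold change (another HOMER measure) were deposited by the authors and were not used. In each form the lists at both times held the same number of peaks in the same order, and every peak overlapped its counterpart. How the lists were matched is not given in the sources used here. Because they are matched peak by peak, their overlap does not test whether places were kept between the times. For the same reason, tests of which peaks and genes are in the full lists at 12 h largely repeat those at 6 h.

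The headers name no scale for the normalized tag counts. HOMER's default of 10000000 tags was assumed. Values in each list fell on an even grid, with 99.0% of the values of Gcr1(U) at 6 h, 97.7% at 12 h, 96.6% of Gcr1(S) at 6 h and 99.6% at 12 h lying within 0.05 units of a step. Chance would place 30.0%, 28.4%, 21.5% and 11.6% there. With the step taken as 0.5 tags, in the same order, 1 unit stood for 1.50, 1.42, 1.07 and 0.582 tags. These factors are also the depths as multiples of the assumed scale, and Gcr1(S) at 12 h was the shallowest. Intervals of a ratio are exact binomial 95% intervals on the pair of tag counts so derived. They rest on that step, they cover counting error only, and PCR reads without molecular identifiers are not independent molecules. They compare pooled libraries and say nothing of the spread between replicates.

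Peak lists were compared by overlap of at least 1 bp. The number of shared peaks was set against 1000 random placements of the second list with the same widths. Placement was made once over the whole of the same chromosome and once on annotated promoters of any nuclear chromosome, with mitochondrial peaks kept on their genome. The smallest permutation p these placements can give is 0.001. At shared peaks the ratio of normalized tag counts was taken, and classes of peaks were summarised by the median and quartiles of the log2 ratio. No p-value was computed across peaks for a condition, because peaks are not replicates. A class median was instead placed among the medians of 10000 random lists of as many peaks matched on mean tags, as a description of these libraries. Each peak of these lists was drawn from the 20 nearest in mean tags in the other classes, without the mitochondrial peaks. Few of those classes' peaks had as many tags as the glycolytic ones, so the matching is loose there. Intervals for differences of Spearman coefficients came from 1000 bootstrap resamples of the peaks.

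Peaks were put in 1 class each: mitochondrial genome, within 500 bp of a nuclear tRNA gene, rDNA, within 10 kb of a chromosome end, promoter of a gene of the glycolysis list, and other nuclear. A gene was assigned to a peak whose centre lay between 1000 bp upstream and 200 bp downstream of its start codon, and a divergent promoter gave both genes. Gene coordinates came from the RefSeq table of the R64 assembly, the assembly that sacCer3 represents, and all 1064 peaks lay inside the extents of its chromosomes. That table gave 6002 nuclear protein-coding genes and 275 nuclear tRNA genes. Chromosome lengths were approximated by the last annotated gene or peak. No genome sequence was used, so the motif tests and the class of LTR and Ty elements were left out.

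Enrichment of 16 gene lists among genes with a peak was tested with Fisher's exact test (two-sided) against all other nuclear protein-coding genes, with Benjamini-Hochberg adjustment over the lists within each peak list and a threshold of 0.05. The lists were glycolysis, ethanol fermentation, ethanol and acetate use, cytosolic ribosomal proteins, translation elongation, gluconeogenesis and glyoxylate cycle, TCA cycle, respiratory chain and ATP synthase, hexose transport and glucose sensing, trehalose and glycogen, heat shock and stress, Gcr1-associated and general regulatory factors, G1 cyclins and start, amino acid and methionine metabolism, plasma membrane and cell wall, and loci altered in the strains. Genes transcribed by RNA polymerase III were counted apart, and those other than tRNA genes had no class of peaks of their own. The lists, the tests and the rule for named genes were fixed before the data were examined. For each comparison that rule takes the genes of the 8 shared peaks with the highest mean tags, of up to 8 peaks with the highest tags found in only 1 list, of the 4 shared peaks with the largest ratio each way, and up to 4 members with a peak of each gene list. Every member of the glycolysis list with a peak is named.

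The alternatives were a reciprocal overlap of 50%, centres within 500 bp, the upper 50% of each list by score, the 100 peaks with the highest score, peaks outside the technical classes, other rules for assigning genes, ratios centred on the median of all shared peaks, and fold over local background in place of tags. Tags per bp of window, centring on peaks at chromosome ends, and a shared lowest value for both forms were added after the lists had been seen. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The steps were tested on simulated data. With lists of 299 peaks and nothing shared, the overlap test called 5.00% of 40 runs, and with 60 shared peaks planted it called 100% of them. Over 6002 genes, the enrichment test called any list in 1.00% of 200 runs with nothing planted and called glycolysis in 100% of runs with 8 of its genes planted. The counting interval of a 2-fold ratio covered the true value in 94.8% of 2000 draws.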

Results

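Binding of Gcr1 was mapped by ChIP-seq in 8 yeast cultures, 2 replicates for each of 4 groups. The groups were Gcr1(U) and Gcr1(S), the forms encoded by the unspliced and the spliced GCR1 transcript, each at 6 h and at 12 h of growth. The 6 h cultures are taken as growing exponentially and the 12 h cultures as past the diauxic shift from glucose to ethanol. No measure of growth phase was analysed here to check this. The data are 1 deposited peak list per form and time, so no value below has a replicate error, and bracketed ranges are 95% intervals for counting error only. Gcr1(U) had 299 peaks and Gcr1(S) 233 at each time. The lowest listed peak had 69.6 normalized tags in Gcr1(U) at 6 h, 69.8 at 12 h, 107.5 in Gcr1(S) at 6 h and 169.3 at 12 h. The usual window was 182 bp in Gcr1(U) at 6 h, 168 bp at 12 h, 170 bp in Gcr1(S) at 6 h and 114 bp at 12 h. Coordinates are those of sacCer3.

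Both forms of Gcr1 were found at the promoters of glycolytic genes. Gcr1(U) had a peak upstream of 8 of the 17 listed genes: PGI1, PFK2, FBA1, TDH3, PGK1, GPM1, ENO2 and CDC19, which encode enzymes from phosphoglucose isomerase to pyruvate kinase. Gcr1(S) had a peak at the same 8 and at TPI1, which encodes triose phosphate isomerase. The peak centres lay between 341 bp (PGI1 and GPM1) and 623 bp (CDC19) upstream of the start codon in Gcr1(U). The CDC19 peak spanned chromosome I 71072 to 71254 and the gene I 71786 to 73288, and the PFK2 peak spanned XIII 675191 to 675373, between PFK2 and the divergent YMR206W. In Gcr1(U) 47.1% of the glycolysis list had a peak against 3.32% of other genes (odds ratio 25.8, adjusted p = 5.21e-07, Fisher's exact test), and in Gcr1(S) at 6 h 52.9% against 2.99% (odds ratio 36.5, adjusted p = 7.52e-09, Fisher's exact test). At 12 h the odds ratio in Gcr1(S) was 37.1 (adjusted p = 6.51e-09, Fisher's exact test), from the same glycolytic genes in the matched list, so it is no second test. Other peak sets and gene assignments moved the odds ratio between 13.5 and 66.5 in Gcr1(U) and between 15.9 and 101 in Gcr1(S), and the list passed in each.

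The most frequent single class of annotated site was the tRNA gene. Gcr1(U) had peaks at 98 of 275 nuclear tRNA genes (35.6%) and Gcr1(S) at 118 (42.9%), and every such peak overlapped the tRNA gene itself. Random placement put a mean of 7.90 peaks of Gcr1(U) and 6.04 of Gcr1(S) within 500 bp of a tRNA gene at 6 h (permutation p = 0.001 for each, the smallest the 1000 placements can give). The forms shared 81 tRNA genes, against 42.1 for independent choices (p = 9.68e-24, Fisher's exact test). Other genes transcribed by RNA polymerase III had peaks too: RPR1 and SNR52 in both forms, SCR1 in Gcr1(U) and SNR6 in Gcr1(S). RPR1 encodes the RNA of RNase P, SCR1 the RNA of the signal recognition particle and SNR6 the U6 spliceosomal RNA. Within 10 kb of a chromosome end lay 61 peaks of Gcr1(U) and 17 of Gcr1(S), 16 of them in no other class, against means of 8.51 and 5.69 by placement at 6 h (permutation p = 0.001 for each). Among the peaks with the highest 50% of scores the enrichment at chromosome ends ended, with permutation p from 0.064 to 0.574 over the 4 lists. The mitochondrial genome held 27 and 26 peaks. At the rDNA 1 peak of Gcr1(U) and 0 of Gcr1(S) were listed (permutation p = 0.368 and 1 by placement at 6 h).

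**Figure D1:**
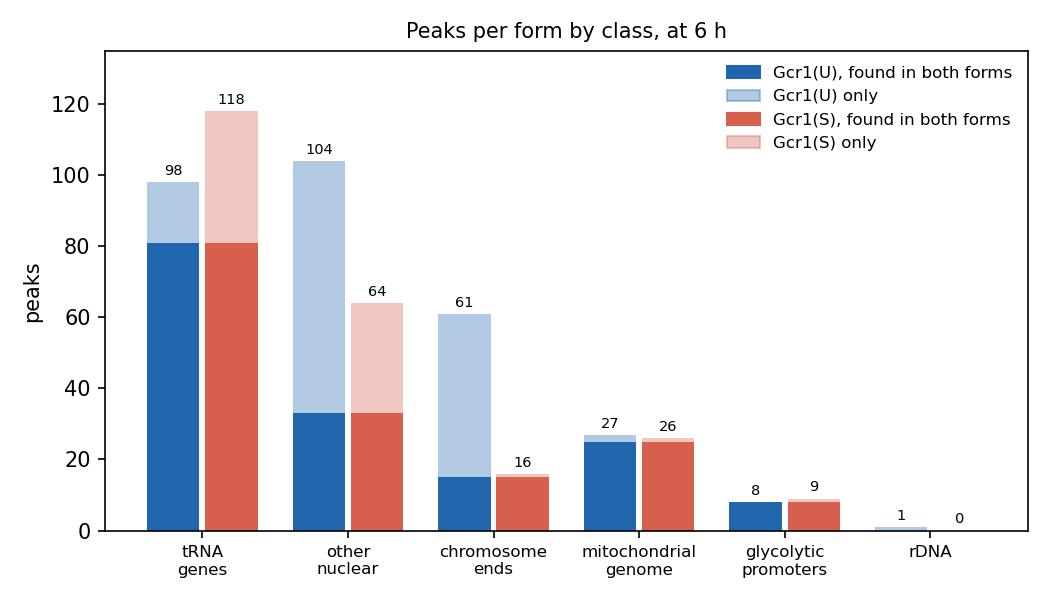
Number of peaks per form at 6 h (vertical axis) in each class of site (horizontal axis), with peaks found in both forms in dark and peaks found in 1 form in light colour. tRNA genes held 98 peaks of Gcr1(U) and 118 of Gcr1(S), with 81 in both, while 15 of the 61 chromosome-end peaks of Gcr1(U) were in both.

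Outside glycolysis few of the fixed gene lists had peaks in number. Cytosolic ribosomal protein genes had 7 of 137 members with a peak in each form (5.11%, adjusted p = 0.427 in Gcr1(U) and 0.485 in Gcr1(S) at 6 h, Fisher's exact test). RPL1B, RPL26A, RPL42B, RPS19B and RPS24A had a peak in both forms, RPL11A and RPL2A in Gcr1(U), and RPL2B and RPL29 in Gcr1(S). The loci altered in the strains had 3 of 7 members with a peak in Gcr1(U) (adjusted p = 0.0102, Fisher's exact test) and 2 of 7 in Gcr1(S) (adjusted p = 0.0985 at 6 h, Fisher's exact test). These members were GCR1 itself and ADH1, the main alcohol dehydrogenase of fermentation, in both forms, and MET17, a methionine synthesis gene whose peak overlapped a tRNA gene, in Gcr1(U). The members were grouped because they are altered in the strains and not by function. How far altered sequence bears on the tags at these loci was not examined. In the upper 50% of the Gcr1(U) peaks by score this list no longer passed, and glycolysis was the only list that did. Ethanol fermentation had ADH1 in both forms and PDC1, pyruvate decarboxylase, in Gcr1(S) (adjusted p = 0.427 and 0.0985 at 6 h, Fisher's exact test). When peaks in the technical classes (tRNA genes, rDNA, chromosome ends, mitochondria) were left out, 4 lists passed the threshold in Gcr1(S): glycolysis, ethanol fermentation and the loci altered in the strains (adjusted p = 0.0170 at 6 h for each of the last pair, Fisher's exact test), and ribosomal protein genes. The latter had an odds ratio of 3.79 at 6 h (adjusted p = 0.0299, Fisher's exact test), and over the alternatives their adjusted p in Gcr1(S) at 6 h went up to 1, as did that of ethanol fermentation, while that of the altered loci went up to 0.541.

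The remaining lists did not pass the test as assigned, but in Gcr1(U) at both times heat shock passed without the technical classes, and hexose transport with the single nearest gene start. The TCA cycle list had SDH1, a succinate dehydrogenase subunit, and CIT1, citrate synthase, in both forms. Translation elongation had EFB1, the respiratory list ATP1, and trehalose and glycogen PGM1, each in both forms. The EFB1 peak, centred 877 bp upstream of EFB1 in Gcr1(U), is the same peak that is counted for SSA1 in the heat shock list. The heat shock list had SSA1 in both, SSA2 and SSB1 in Gcr1(U), and SOD2, the mitochondrial superoxide dismutase, in Gcr1(S). The peaks at SSA1, SSA2 and SSB1 were centred inside the genes and not upstream of them. Amino acid metabolism had ASN2 and GCN4 in both forms and MET17 in Gcr1(U), and the regulatory factors had GCR1 in both and PHO4 in Gcr1(U). The hexose transporter genes HXT9 and HXT11 had a peak in Gcr1(U), and WHI5, an inhibitor of the start of the cell cycle, in Gcr1(S). The HXT9 peak was centred inside the gene. At 12 h HXT9 had 118 tags and HXT11 143 in Gcr1(U), under the lowest value listed for Gcr1(S), 169.3. The peaks at CIT1, ATP1, PGM1, ASN2, MET17, PHO4 and RPL26A lay within 500 bp of a tRNA gene. Ethanol and acetate use, gluconeogenesis and the glyoxylate cycle, and plasma membrane and cell wall had 0 members with a peak in either form.

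The comparison of forms at 6 h asks whether both forms occupy the same places during exponential growth. Glycolytic promoters had fewer tags in Gcr1(S) than in Gcr1(U), with a median ratio of 0.707 over 8 promoters, or a log2 ratio of -0.50 (quartiles -0.72 and -0.19). FBA1, aldolase, had 1417 tags in Gcr1(U) and 673 in Gcr1(S), a ratio of 0.475 (0.436 to 0.517). PFK2, a phosphofructokinase subunit, had a ratio of 0.525 (0.488 to 0.564) and ADH1 one of 0.467 (0.445 to 0.489), from 4497 to 2099 tags. The ratios at GPM1 (1.07, 0.994 to 1.14) and PGK1 (0.930, 0.839 to 1.03) were not separable from 1 at this depth, though both lay below it after centring. tRNA genes went the other way, with more tags in Gcr1(S) at all 81 shared sites and a median log2 ratio of 0.50 (quartiles 0.39 and 0.58). The interval lay above 1 at 79 of them as normalized, but after centring at 32, with 1 below and 48 spanning 1.

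Of the peaks at 6 h, 162 were shared, 54.2% of those of Gcr1(U) and 69.5% of those of Gcr1(S). Placement on annotated promoters gave a mean of 4.92 shared peaks and a maximum of 12 (permutation p = 0.001, the smallest the 1000 placements can give). The highest shared peak lay at IX 242110 to 242292, within EFM4 and in the promoter range of the divergent FIS1, with 6110 tags in Gcr1(U) and 8687 in Gcr1(S). CIS1 (2051 and 2203 tags, lower in Gcr1(S) after centring), a site inside RAD34 at IV 1092090 to 1092272 (1801 and 2312 tags), CDC19 (1760 and 1517) and PGI1 (1674 and 1298) followed among the highest. The largest ratios were at peaks near RHB1 (1.83, 1.61 to 2.08), HIT1 (1.68, 1.49 to 1.90), PMD1 (1.67, 1.49 to 1.88) and PSH1 (1.66, 1.46 to 1.89), and those at RHB1, HIT1 and PSH1 overlapped tRNA genes. The smallest ratio was at a mitochondrial site inside COX1 (0.435, 0.403 to 0.470), and all 25 shared mitochondrial peaks were lower in Gcr1(S), with a median log2 ratio of -0.77 that turned to 0.11 with fold over local background. Chromosome-end peaks (median 0.03) and other nuclear peaks (0.10) went both ways. Centring turned these medians to -0.32 and -0.25, with intervals above and below 1 going from 5 and 3 to 1 and 10 at chromosome ends, and from 14 and 7 to 4 and 18 at other nuclear peaks.

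Among peaks found in 1 form at 6 h, the highest in Gcr1(U) with an assigned or overlapped gene other than a tRNA were at SCR1 (943 tags), RPL2A (414), FYV6 and KRE33 (354), MCM3 (350.0), CLU1 (348.0), PHO4 and CDC26 (342), and RPL11A and PRE2 (325). In Gcr1(S) they were at SNR6 (588.0), MRPL10 (494), YFL019C (493), TPI1 (492), RSM26 and AIM25 (487) and PDC1 (486), besides tRNA sites with no assigned gene. The peaks at FYV6, MCM3, CLU1, PHO4, MRPL10, YFL019C and RSM26 overlapped tRNA genes. Of the 137 peaks of Gcr1(U) alone, 101 (73.7%) lay under the lowest value listed for Gcr1(S) at either time. For the 71 of Gcr1(S) alone the count was 0 by construction, since every listed value of Gcr1(S) lay above the lowest of Gcr1(U). These counts use unscaled tags, 11 mitochondrial peaks under the same limit were shared nonetheless, and scaling by the ratio of the forms at shared peaks took other nuclear peaks under a limit from 58 to 26 of 71. The lowest fold over local background listed for Gcr1(U) was 2.00 at 6 h and 2.01 at 12 h. The peaks of Gcr1(S) alone were not set against that limit, so a detection limit of the Gcr1(U) lists stays open for them. No gene list differed between genes with a peak in Gcr1(U) alone and genes with a peak in both (16 lists, 0 past the threshold by Fisher's exact test, 0 at an unadjusted p under 0.05, lowest adjusted p = 0.841). For Gcr1(S) alone both counts were 0 too. Over all shared peaks the interval lay above 1 at 98 and below 1 at 41. Centring on the median of all shared peaks, which shifts every log2 ratio by the median of 0.36, made this 37 and 62, and tags per bp made it 104 and 36.

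At 12 h the order of the forms was the opposite. All 8 shared glycolytic promoters had more tags in Gcr1(S), with a median ratio of 2.83, or a log2 ratio of 1.50 (quartiles 1.20 and 1.67). ENO2, enolase, had 478 tags in Gcr1(U) and 1670 in Gcr1(S), a ratio of 3.50 (3.17 to 3.86), and the smallest of the 8 was at CDC19, pyruvate kinase (1.82, 1.70 to 1.96). TDH3, glyceraldehyde-3-phosphate dehydrogenase, had a ratio of 3.30 (2.97 to 3.68) and ADH1 one of 1.61 (1.51 to 1.72). All 81 shared tRNA genes had fewer tags in Gcr1(S), with a median ratio of 0.547, or a log2 ratio of -0.87 (quartiles -0.99 and -0.75). After centring the tRNA median was -0.27, with 40 intervals below 1 and 41 spanning it, and per bp it was -0.31, with 48 below. Centring put the glycolytic median at 2.10. The glycolytic median lay at percentile 99.7 of random lists of loosely matched peaks, which leave out the mitochondrial peaks. Strong peaks outside glycolysis differed, with ratios of 3.71 at EFM4, 3.56 near CCR4 and 1.97 at CIS1. The peak upstream of YGL081W went the other way, with 1249 tags in Gcr1(U) and 779 in Gcr1(S). The percentile therefore does not make the change particular to glycolysis.

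The lists at 12 h shared 163 peaks, 54.5% of those of Gcr1(U) and 70.0% of those of Gcr1(S), against a mean of 3.97 and a maximum of 11 for placement on promoters (permutation p = 0.001, the smallest the 1000 placements can give). With the lists of each form matched across times, this repeats the overlap at 6 h. The EFM4 peak had 4158 tags in Gcr1(U) and 15419 in Gcr1(S), a ratio of 3.71 (3.59 to 3.83). The site inside RAD34 (2.64, 2.49 to 2.81), CIS1 (1.97, 1.86 to 2.09) and a site inside ATS1 near CCR4 and FUN30 (3.56, 3.24 to 3.93) were also higher in Gcr1(S). The smallest ratios were at peaks overlapping tRNA genes, near VMA3 (0.415, 0.339 to 0.506), HIT1 (0.422, 0.347 to 0.510), SES1 and ATG31 (0.435, 0.360 to 0.526), and COQ6 and GND2 (0.446, 0.364 to 0.548). All 25 shared mitochondrial peaks were higher in Gcr1(S), with a median log2 ratio of 1.08 and the largest at a site inside COB (4.84, 3.80 to 6.21). With fold over local background that median turned to -0.37.

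Among peaks of Gcr1(S) alone at 12 h, BMH1, which encodes a 14-3-3 protein, had 1496 tags, TPI1 907, BST1 761, WHI5 and TGL5 677, SOD2 659 and GPR1, a glucose-sensing receptor gene, 654. Among those of Gcr1(U) alone, SCR1 had 876, MCM3 472, CLU1 448, PHO4 and CDC26 430, CTK2 and CYR1 425, PFU1 and PMT7 417, and FYV6 and KRE33 416, with all but SCR1 within 500 bp of a tRNA gene. No gene list passed the test of genes with a peak in 1 form against genes with a peak in both. By Fisher's exact test 0 of 16 passed in each direction (0 at an unadjusted p under 0.05, lowest adjusted p = 0.843, or 0.841 with centres within 500 bp). Between the upper 50% of each list by score, glycolysis had 0 members among genes in that of Gcr1(U) only and 8 among genes in both (adjusted p = 0.0125, Fisher's exact test). Such genes may still have a lower-ranked peak in Gcr1(S), so this does not show binding by 1 form. At 12 h tRNA peaks lay above the list median in Gcr1(U) (medians 405 and 288 tags) and below it in Gcr1(S) (220 and 250). Over all shared peaks the interval lay above 1 at 52 and below 1 at 92. Centring, which shifts log2 ratios by the median of -0.60, made this 73 and 42, and tags per bp made it 72 and 50.

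Within Gcr1(U), the comparison of times asks whether this form keeps its places through the diauxic shift. All 8 glycolytic promoters had fewer tags at 12 h than at 6 h, with a median ratio of 0.474, or a log2 ratio of -1.08 (quartiles -1.32 and -0.53). The ratio was 0.341 (0.313 to 0.372) at FBA1, from 1417 to 484 tags, and 0.701 (0.659 to 0.744) at CDC19, from 1760 to 1233. ADH1 had 4497 tags at 6 h and 1706 at 12 h, a ratio of 0.379 (0.362 to 0.397). Of the 98 tRNA peaks 94 were higher at 12 h, 82 of them with an interval above 1, with a median ratio of 1.26 (log2 0.33, quartiles 0.24 and 0.42).

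The glycolytic median of Gcr1(U) lay below the central 95% of medians of matched random lists (-0.30 to 0.43). Mitochondrial peaks, which these lists leave out, had a median lower still, at -1.26. GCR1's own promoter, at XVI 411982 to 412164, had 420 tags at 6 h and 302 at 12 h (ratio 0.718, 0.634 to 0.814), and SDH1 had a ratio of 0.623 (0.558 to 0.695). EFM4 (0.681, 0.659 to 0.703), CIS1 (0.856, 0.811 to 0.902) and the site inside RAD34 (0.811, 0.766 to 0.860) were lower at 12 h (all 3 higher by fold over local background, at log2 0.12, 0.28 and 0.10), and a peak inside MIY3 and upstream of YGL081W was not separable from 1 (1.04, 0.976 to 1.11). The largest ratios were at sites inside RPL8A (1.99, 1.72 to 2.31, log2 0.12 by fold over local background) and ENO2 (1.98, 1.70 to 2.31), at the tRNA gene YNCD0005C (1.70, 1.50 to 1.93) and near HIT1 (1.66, 1.47 to 1.86). All 27 mitochondrial peaks were lower at 12 h, with a median log2 ratio of -1.26 and the smallest ratio at COB (0.201, 0.160 to 0.247). With fold over local background that median turned to 0.46, above 0 at 26 of 27. The mitochondrial share of peak tags was 14.6% at 6 h and 6.49% at 12 h. The 7 ribosomal protein genes had a median log2 ratio of -0.13, with 1 interval above 1, 2 below and 4 spanning it. Every peak overlapped its counterpart at the other time, in lists that are matched peak by peak. Over all 299 peaks the interval lay above 1 at 99 and below 1 at 65. Centring made this 93 and 77, and tags per bp 122 and 54.

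**Figure D2:**
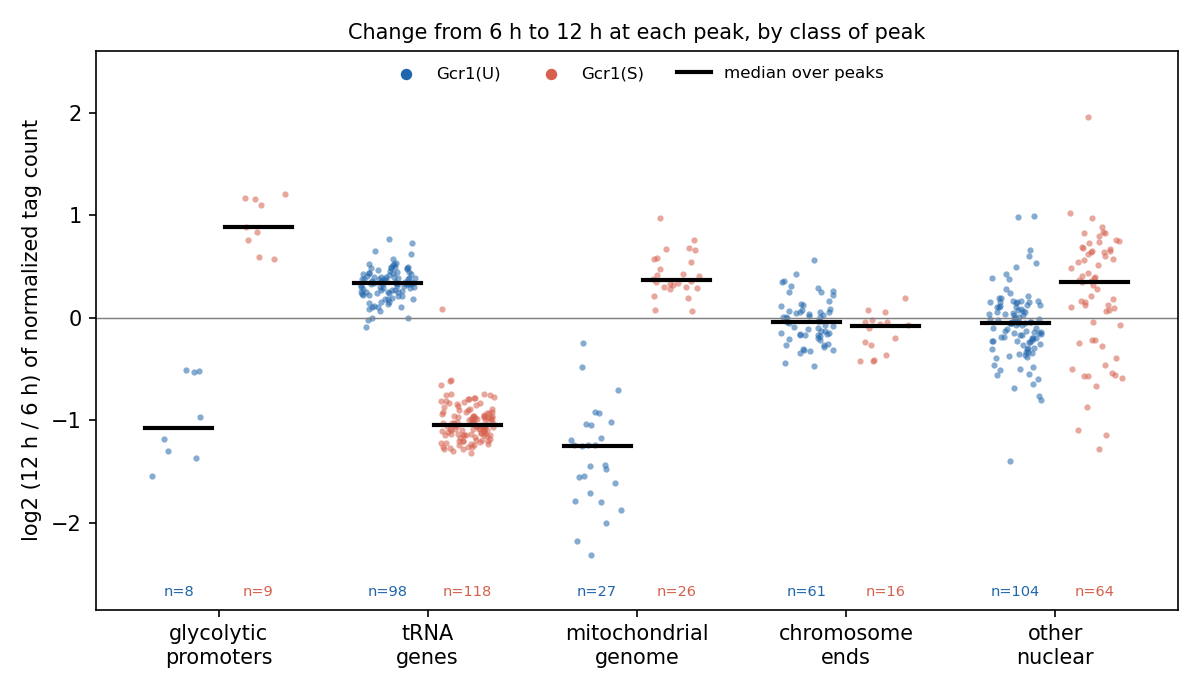
Change from 6 h to 12 h at each peak (vertical axis, log2 ratio of normalized tag counts) by class of site (horizontal axis), Gcr1(U) in blue and Gcr1(S) in red, each point 1 peak and each bar the median. The median was -1.08 in Gcr1(U) and 0.88 in Gcr1(S) at glycolytic promoters, and 0.33 and -1.04 at tRNA genes, directions that held under centring and per bp, while the chromosome-end median of Gcr1(S), -0.09, became 0.66 when centred and 0.44 per bp.

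Within Gcr1(S), glycolytic promoters had more tags at 12 h. The ratio was above 1 at all 9, with a median of 1.84, or a log2 ratio of 0.88 (quartiles 0.75 and 1.16). PFK2 had 973 tags at 6 h and 2249 at 12 h, a ratio of 2.31 (2.13 to 2.51), and TDH3 (2.25, 2.03 to 2.50) and ENO2 (2.23, 2.03 to 2.46) came next. CDC19 had the smallest ratio of the 9 (1.48, 1.38 to 1.59), TPI1 had 492 and 907 tags (1.84, 1.63 to 2.09), and ADH1 a ratio of 1.31 (1.23 to 1.40). At tRNA genes 117 of 118 peaks were lower at 12 h, with a median ratio of 0.485 (log2 -1.04, quartiles -1.14 and -0.93). After centring the tRNA median was -0.30, with 63 intervals below 1, 1 above and 54 spanning it, and per bp it was -0.47, with 98 below. Centring put the glycolytic median at 1.63.

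The largest ratio in Gcr1(S) was at BMH1, V 545195 to 545365, from 385 to 1496 tags (3.89, 3.46 to 4.39). GCR1 (1.48, 1.28 to 1.70), SDH1 (1.54, 1.35 to 1.76), WHI5 (1.84, 1.60 to 2.12), SOD2 (1.49, 1.29 to 1.70), EFM4 (1.77, 1.72 to 1.83), CIS1 (1.57, 1.48 to 1.67) and the site inside RAD34 (1.67, 1.58 to 1.77) were higher at 12 h (EFM4 and the RAD34 site lower by fold over local background, at log2 -1.47 and -0.29). PDC1 was not separable from 1 as normalized (1.11, 0.959 to 1.28). It was higher at 12 h when centred (log2 0.90), per bp (0.73) and by fold over local background, which went from 2.77 to 4.02. The smallest ratios were near PSH1 (0.399, 0.322 to 0.491), at the tRNA gene YNCC0014W (0.407, 0.325 to 0.505), near VMA3 (0.410, 0.332 to 0.501) and upstream of PMD1 (0.410, 0.340 to 0.493). The 26 mitochondrial peaks had a median log2 ratio of 0.36 (-0.0079 with fold over local background), and the mitochondrial share of peak tags was 7.62% at 6 h and 10.1% at 12 h. The 7 ribosomal protein genes had a median log2 ratio of -0.50, with 0 intervals above 1, 5 below and 2 spanning it, but that median turned to 0.25 when centred, with 6 of the 7 positive, to 0.079 per bp and to 0.070 with fold over local background, with 5 of the 7 positive in each. As in Gcr1(U), every peak overlapped its counterpart in the matched lists. Over all 233 peaks the interval lay above 1 at 65 and below 1 at 137. Centring, which shifts log2 ratios by the median of -0.75, made this 106 and 66, and tags per bp 99 and 102.

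**Figure D3:**
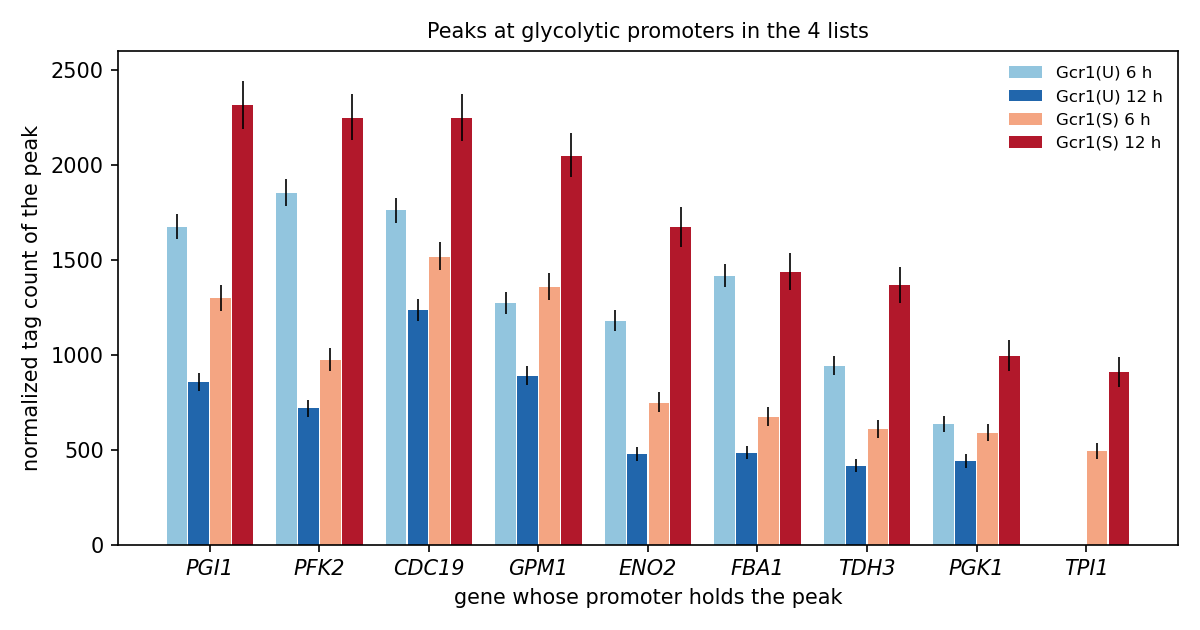
Normalized tag count of the peak (vertical axis, from 0) at each glycolytic promoter (horizontal axis) in the 4 lists, with bars for form and time and lines for the 95% counting interval. At PGI1 the count went from 1674 at 6 h to 857 at 12 h in Gcr1(U) and from 1298 to 2313 in Gcr1(S), and TPI1 had a peak in Gcr1(S) only.

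The course over time thus had opposite signs in the forms at most shared peaks. Of the 162 shared peaks 144 had opposite signs, 55 lower at 12 h in Gcr1(U) and higher in Gcr1(S), and 89 the reverse. The change in Gcr1(S) minus that in Gcr1(U) had a median log2 value of 2.08 at the 8 glycolytic promoters (quartiles 1.24 and 2.49), of -1.39 at the 81 tRNA genes (quartiles -1.52 and -1.17) and of 1.83 at the 25 mitochondrial sites (quartiles 1.53 and 2.13). At other nuclear peaks it was 0.77 (1.55 when centred), and at chromosome ends -0.13, which turned to 0.65 when centred and 0.33 per bp. The mitochondrial value was -0.42 when fold over local background replaced tags, and centring moved the values to 2.86 at glycolytic promoters, -0.60 at tRNA genes and 2.62 at mitochondrial sites. Across all shared peaks, which are not independent replicates, tags of Gcr1(U) at 6 h correlated with those of Gcr1(S) at 12 h at a Spearman coefficient of 0.827, and Gcr1(U) at 12 h with Gcr1(S) at 6 h at 0.907. Pairs of the same time had 0.677 at 6 h and 0.339 at 12 h. Within classes the crossed pairs led at tRNA genes (0.779 and 0.867, against 0.685 and 0.619). At mitochondrial sites the same-time pairs had 0.966 at 6 h and 0.892 at 12 h, against 0.962 and 0.914 for the crossed pairs. At the 56 peaks of neither class they had 0.931 and 0.779, against 0.897 and 0.936. No replicate error was at hand to test these differences.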

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

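Every test in this part was chosen only after the results it bears on had been seen.

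At shared glycolytic promoters, tRNA genes and mitochondrial sites the change from 6 h to 12 h ran in opposite directions in Gcr1(U) and Gcr1(S), with a difference of 2.08, -1.39 and 1.83 on the log2 scale (Gcr1(S) minus Gcr1(U), medians over 8, 81 and 25 peaks). Opposite directions at these classes drew attention to them, at 8 of 8, 77 of 81 and 25 of 25 peaks, and the difference itself was not tested, because there is 1 pooled value per form and time.

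For the glycolytic promoters and tRNA genes, a change of library scale or depth would move all classes of a form by 1 factor. As the whole cause in both classes this was excluded: the glycolytic median less the tRNA median was -1.41 in Gcr1(U), against a combined SD over peaks of 0.45, and 1.93 in Gcr1(S), against 0.31. A change of scale as part of the change in either class stays open, since this difference cannot show it. The narrower windows of Gcr1(S) at 12 h were excluded as the whole cause too, since per bp the difference between the forms stayed at -0.93 at tRNA genes (SD 0.28) and 2.54 at glycolytic promoters (SD 0.68). An exchange of the 6 h and 12 h lists of 1 form stays open as a candidate explanation: over all shared peaks, lists of different form and time had Spearman coefficients of 0.827 and 0.907, against 0.677 and 0.339 for lists of the same time, and at tRNA genes the highest were 0.867 and 0.685. In the other peaks the crossed pairs led the same-time pair at 12 h (mitochondrial sites 0.962 and 0.914 against 0.892, the 56 remaining peaks 0.897 and 0.936 against 0.779) but were not separable from the pair at 6 h, with 0.966 less 0.962 at 0.0048 (95% bootstrap interval over peaks -0.065 to 0.067) and 0.931 less 0.936 at -0.0052 (-0.053 to 0.039). A true opposite course of the forms through the diauxic shift, which was not tested, gives the same values, so both cannot be told apart without values per replicate or a marker of culture age.

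At mitochondrial sites the tags and the fold over local background parted. In Gcr1(U), where tags had a median log2 ratio of -1.26 from 6 h to 12 h, the fold had a median of 0.46 (SD 0.37) and was above 0 at 26 of 27 peaks, so the background fell by more than the tags. A loss of signal at single mitochondrial sites needs a value below 0, and a changed share of mitochondrial DNA as the whole cause needs a value near 0. In Gcr1(U) the same 0.46 argued against both at the listed sites, though its SD is over peaks of pooled lists and not over replicates. The lists of Gcr1(U) held no peak under a fold of 2.00 at 6 h and 2.01 at 12 h. A site whose fold fell below that limit would be missing, so loss at such sites cannot be judged. In Gcr1(S) the median was -0.0079 for the fold (SD 0.39) and 0.36 for the tags per window, a gap within the spread. The usual window narrowed there from 170 bp at 6 h to 114 bp at 12 h. Per bp the median of the tags was 0.94, a gap beyond the SD. The values per bp thus go with a changed share, while those per window cannot tell it from a change at single sites. A changed share as part of the cause stays open in both forms, and no biological explanation was tested.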

How the results depend on the processing

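Tags per bp, centring on chromosome-end peaks, a shared lowest value for both forms and every alternative for the difference between the forms and for the median of the ribosomal protein list were chosen only after the data had been seen. Of 275 alternative values of main results, 217 stayed within 1 SD or on their side of the threshold, 44 moved, 2 passed the threshold, 4 lost it and 8 changed the sign of a median whose quartiles lay on 1 side of 0. Another 14 sign changes, among those that moved (7) or stayed within 1 SD (7), were at medians whose quartiles spanned 0, and all 22 are given below. The overlap of forms stayed at a permutation p = 0.001, the smallest that 1000 placements can give, in every alternative. Glycolytic promoters and tRNA genes kept their direction in every alternative of all 4 comparisons. Of 447 alternative values at named genes and sites and of the ribosomal protein median, 136 stayed within their interval or spread and 274 moved. The other 37 changed the sign of a value whose interval or quartiles lay on 1 side of 0. Sign changes at values whose interval or quartiles spanned 0, such as GPM1 between forms at 6 h when centred, were not counted apart. Except where the construction shows it, the cause was not tested. Depth limits Gcr1(S) at 12 h most, with the fewest tags per unit and the highest lowest value.

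Centring subtracts the median of all shared peaks (log2), by construction. tRNA genes made up 81 of the 162 peaks shared between forms at 6 h and 118 of the 233 of Gcr1(S). In Gcr1(S) and between the forms the subtracted median therefore leans to the tRNA change. Over time in Gcr1(S) it was -0.75, against -1.04 at tRNA genes, -0.09 at chromosome ends and 0.35 at other nuclear sites. Gcr1(S) over Gcr1(U) became 0.14 at tRNA genes, -1.13 at mitochondrial sites and, with their signs changed, -0.32 at chromosome ends and -0.25 at other nuclear sites at 6 h, and 2.10 at glycolytic promoters, -0.27 at tRNA genes, 1.68 at mitochondrial sites and, with its sign changed, 0.55 at chromosome ends at 12 h. The ratio of times in Gcr1(S) became 1.63 at glycolytic promoters, -0.30 at tRNA genes, 1.11 at mitochondrial sites, 1.10 at other nuclear sites and, with its sign changed, 0.66 at chromosome ends. The difference between the forms became 2.86 at glycolytic promoters, -0.60 at tRNA genes, 2.62 at mitochondrial sites and, with its sign changed, 0.65 at chromosome ends. The ribosomal protein median changed sign to 0.039 between forms at 12 h and 0.25 over time in Gcr1(S), and RPL2B to 0.16. RPS24A changed sign to -0.13 between forms at 6 h, 0.20 at 12 h and 0.17 over time in Gcr1(S), RPS19B to 0.039 at 12 h and 0.29 over time, and RPL1B to 0.25 over time. CIS1 changed sign to -0.25 and COQ6 to -0.16 between forms at 6 h, and YGL081W to 0.19 and GPD2 to 0.078 over time in Gcr1(S).

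With fold over local background, mitochondrial sites changed sign to 0.11 between forms at 6 h, -0.37 at 12 h, 0.46 over time in Gcr1(U), -0.0079 in Gcr1(S) and -0.42 for the difference. Chromosome ends became 0.41 between forms at 6 h and changed sign to 0.37 at 12 h, 0.081 over time in Gcr1(U) and 0.072 in Gcr1(S), and other nuclear sites to 0.075 in Gcr1(U). Glycolytic promoters became 1.10 and tRNA genes -0.20 between forms at 12 h, and tRNA genes -0.32 over time in Gcr1(S) and -0.58 for the difference. RPL1B changed sign to 0.070, RPS19B to 0.16, EFM4 to -1.47 and GPP1 to -0.024 over time in Gcr1(S), EFM4 to 0.12 and CIS1 to 0.28 over time in Gcr1(U), SDH1 to 0.62 and GPP1 to 0.14 between forms at 6 h, and YGL081W to 0.061 at 12 h. RPL2B changed sign to 0.038, the ribosomal protein median to 0.070 and the sites inside RAD34 to -0.29 and COX1 to -0.19 over time in Gcr1(S). In Gcr1(U) the sites inside RAD34, COX1 and COB changed sign to 0.10, 0.36 and 0.35, and between forms COB to 0.13 at 6 h and COX1 to -0.20 at 12 h.

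Per bp, between forms at 12 h glycolytic promoters became 2.06, tRNA genes -0.31, mitochondrial sites 1.64 and, with the sign changed, chromosome ends 0.51. Over time in Gcr1(U) chromosome ends changed sign to 0.078 and other nuclear sites to 0.061. Over time in Gcr1(S) they became 1.46, -0.47, 0.94 and, with the sign changed, 0.44, and the difference -0.93 at tRNA genes and, with the sign changed, 0.33 at chromosome ends. RPS24A changed sign to 0.16 between forms at 12 h and 0.0015 over time in Gcr1(S), RPL1B and the ribosomal protein median to 0.079, RPS19B to 0.12 and YGL081W to 0.017.

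In the upper 50% of each list, which holds fewer peaks by construction, chromosome ends became 0.49 between forms at 6 h, -0.36 over time in Gcr1(S) and -0.59 for the difference. The median over time changed sign to 0.072 over all peaks of Gcr1(S), from -0.75, and to 0.16 at chromosome ends of Gcr1(U). With a reciprocal overlap of 50%, chromosome ends between forms at 12 h went from -0.05 to 0.00034. The share at chromosome ends became 4.0% in Gcr1(U) at 6 h (p = 0.165) and at 12 h (p = 0.183), 2.56% in Gcr1(S) at 6 h (p = 0.574) and 5.13% at 12 h (p = 0.064), all permutation p-values by random placement. Mitochondrial shares became 5.98% in Gcr1(S) at 6 h, 4.67% in Gcr1(U) at 12 h and 17.9% in Gcr1(S) at 12 h. Gene lists past the threshold went from 2 to 1 in Gcr1(U) at both times, with the loci altered in the strains lost, and from 1 to 2 in Gcr1(S) at 6 h, with ethanol fermentation added, and to 3 at 12 h, with the loci altered in the strains added too. Glycolysis then differed at 12 h between genes in the upper 50% of Gcr1(U) only and those in the upper 50% of both forms (1 list, adjusted p = 0.0125, Fisher's exact test). Genes of the first kind may still have a lower-ranked peak in Gcr1(S). Without the technical classes 4 lists passed in Gcr1(S) at each time, and ribosomal protein genes had odds ratios of 3.79 at 6 h (adjusted p = 0.0299, Fisher's exact test) and 3.85 at 12 h (adjusted p = 0.0281, Fisher's exact test).

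No paired analysis was possible because each list pools its replicates, and for the same reason the replicate block and leaving out a replicate were not run. The Gcr1 and Rap1 motif tests and their alternatives were not run, since no genome sequence was used.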

Other observations

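The tests of peaks found in Gcr1(U) alone were chosen only after these peaks had been seen.

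The genes GPD1, GPP1 and GPD2 are in none of the fixed lists and were singled out after their values were seen, so they stand as single genes and not as a tested group. GPD1, glycerol-3-phosphate dehydrogenase, had 578 tags at 6 h and 370 at 12 h in Gcr1(U) (ratio 0.639, 0.573 to 0.713) and 384 and 546 in Gcr1(S) (1.42, 1.22 to 1.65). GPP1, glycerol-1-phosphatase, had 971 and 659 in Gcr1(U) (0.679, 0.625 to 0.738) and 821 and 1051 in Gcr1(S) (1.28, 1.15 to 1.42), where fold over local background gave a log2 ratio of -0.024. GPD2, the paralog of GPD1, had 662 and 1006 in Gcr1(U) (1.52, 1.40 to 1.65) and 970 and 609 in Gcr1(S) (0.628, 0.556 to 0.710), at a peak that lies between GPD2 and MAM3. The direction at GPD2 in Gcr1(S) depends on the scaling, with a log2 ratio of -0.67 as normalized, 0.078 when centred and -0.094 per bp.

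Peaks found in Gcr1(U) alone may reflect the detection limit of the Gcr1(S) lists, and the tests left this open in each class. Values of Gcr1(U) were scaled by the median ratio of the forms at shared peaks of the class and set against the lowest tags and the lowest fold over local background listed for Gcr1(S). At chromosome ends 41 of 46 such peaks lay under a limit at 6 h or 12 h (from 35 to 46 with the ratio moved by 1 SD each way), at other nuclear sites 26 of 71 (3 to 67) and at tRNA genes 5 of 17 (0 to 13). The ratios at shared peaks spread too widely to decide.

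The number in each peak's identifier fell as its tags rose on every chromosome, with Spearman coefficients from -1 to -0.90 across peaks. Summed over chromosomes, the highest numbers came to 12916 in Gcr1(U) at 6 h, 14206 at 12 h, 1303 in Gcr1(S) at 6 h and 774 at 12 h, of which the listed peaks are 2.32%, 2.10%, 17.9% and 30.1%.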
